A study of Mus musculus with 3 samples.

How the data were processed

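Mature miRNAs were measured in 3 samples of cultured mouse bone marrow cells, 1 each of bone marrow macrophages (BMM), preosteoclasts (pOC) and mature osteoclasts (mOC). Per the labels' protocols, marrow cells were cultured for 24 h, floating cells received M-CSF at 50 ng/mL for 72 h to give BMM, and these received M-CSF at 30 ng/mL with RANKL at 100 ng/mL for 24 h (pOC) or for 72 h or more (mOC). Alendronate at 500 µM was added for 12 h at 80 to 90% confluence. Groups were taken from the sample labels. The vesicle fraction, the library kit and its size selection, the trimming, the miRNA annotation release and the treatment of reads that match several loci are not given in the sources used here. The submitters' processing notes name FastQC, HISAT2 and StringTie, without versions or roles, and the genome build GRCm38.

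The 9 deposited tables hold 3 comparisons (mOC against R, pOC against mOC, pOC against R), each with all 899 miRNAs and with the authors' higher and lower ones. Per the file headers, the authors deposited raw read counts per miRNA, which are whole numbers that sum to a different total in each library. The authors also deposited normalised counts, treated here as a score: each is the raw count divided by 1 constant per library and multiplied by 1000000. That constant was 4803435 for pOC and 5139860 for mOC, so the raw totals are 1.13 and 1.37 times as large, and the authors' values are not CPM of these tables. Per the file headers, the remaining columns are the authors' log2 fold change, the fold change as a ratio and an unadjusted p-value. The direction is the first library named over the second, checked on the counts of pOC and mOC.

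Columns were matched to samples by name alone, POC to the pOC sample and OC to the mOC sample. No label spells out R, and no column carries the name of the BMM sample, so R was matched to no sample and its counts were not used. The comparisons planned with BMM were therefore replaced by the authors' fold changes over R, with no interval of their own and no count minimum. Of 36 per-sample columns 30 were not used, 12 of them headed R and 18 repeats of pOC or mOC columns. Both repeated count columns that were compared were identical to those used.

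With 1 library per group, no test with replicates was possible. The only test across libraries was the edgeR exact test described below, run with assumed dispersions. For mOC against pOC, counts were scaled to the library totals and a log2 ratio was taken with a pseudocount of 1 count scaled to each library. The 95% interval of each fold is the exact Clopper-Pearson binomial interval of the 2 counts, and the limit for a count of 0 is 3 counts. Intervals and limits cover counting error only, not the spread between cultures or libraries, and reads without molecular identifiers are not independent molecules. A miRNA was called higher or lower with an absolute log2 ratio of at least 1, at least 10 counts over both libraries and an interval that excludes 1. Abundant miRNAs carry narrow intervals: 11089 against 2876 counts gave 4.78 to 5.19-fold for miR-122-5p, while 63 against 20 counts gave 2.43 to 7.11-fold for miR-214-3p.

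The authors' thresholds were read from their tables. Each list of higher or lower miRNAs held exactly those with an absolute log2 fold change of at least 1 and a p-value under 0.05. The exact test of edgeR with TMM scaling and a fixed dispersion of 0.01, a biological coefficient of variation of 0.1, rebuilt the deposited log2 fold changes of pOC over mOC within 0.001 and the p-values within 1% for 899 of 899 miRNAs. The p-values therefore rest on that assumed dispersion and compare these libraries, not the conditions.

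Before the data were examined, 27 lists of miRNAs were fixed, by described role in osteoclasts, family or genomic cluster, and as markers of other cell types or sources (erythroid, lymphoid, stromal, endothelial, platelet, epithelial, liver or serum, muscle and neural). The median log2 ratio of each list's members with at least 10 counts was placed as a percentile among 10000 random lists of the same size and abundance. For the comparisons with R as well, abundance and this minimum were taken from pOC and mOC together, since the counts of R were not used. These percentiles describe the libraries and are no test of the conditions. Members overlap between some lists. The named miRNAs were also chosen by a rule fixed beforehand. They are the 8 largest increases and 8 largest decreases per comparison among called miRNAs with at least 50 counts in 1 of the libraries, and up to 4 members of each of the osteoclast-promoting, osteoclast-restraining, inflammatory macrophage and myeloid lists by absolute log2 ratio. Against R the minimum was applied to pOC or to mOC alone, since the counts of R were not used. miRNAs abundant in R but scarce in the other library could therefore not be named. The 5 most abundant miRNAs of each library, miR-214-3p, miR-23a-5p, miR-155-5p, miR-223-3p and miR-21a-5p were added. Examples given for the other lists were chosen after their values were seen.

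Hairpin positions and host genes came from the GENCODE vM21 annotation of GRCm38, matched by miRNA name, which found 875 of 899 miRNAs and 330 of the 337 abundant ones. Among the abundant ones 27 have several loci. Host genes are those annotated on the same strand. Members of the let-7 family, miR-486a and miR-486b, and miRNAs with several loci such as miR-26a-5p, miR-129-5p, miR-450a-5p and miR-133a-3p are uncertain where reads match several copies. In 4 groups of miRNAs with at least 50 counts over both libraries, the counts were identical. Reads counted under several names, or split evenly, would give this. miR-199a-3p and miR-199b-3p, for example, had the same log2 ratio of mOC over pOC (0.09).

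The calling rule was tested on 20 simulated pairs of the pOC and mOC libraries per setting, with 200 of the 899 miRNAs changed outside the 50 most abundant. At a coefficient of variation of 0.1 it recovered 42.5% of 2-fold, 89.0% of 4-fold and 91.0% of 8-fold changes and called 1.90% of unchanged miRNAs. At 0.4 the shares were 44.2%, 74.2%, 89.0% and 22.9%. Alternatives were other scalings, pseudocounts, count minimums and fold thresholds, a stricter threshold on the authors' calls and, chosen after the data were seen, the authors' constants, larger dispersions, a count minimum and recentring for the comparisons with R. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.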

Results

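The abundance of mature miRNAs was profiled by sequencing in mouse cultures that represent 3 stages of osteoclast formation, the process in which macrophages of the bone marrow fuse into the cells that resorb bone. Marrow was taken from C57BL/6 mice of 11 weeks. Bone marrow macrophages (BMM) were grown with the macrophage growth factor M-CSF, preosteoclasts (pOC) were made from them with M-CSF and the osteoclast-inducing cytokine RANKL over 24 h, and mature osteoclasts (mOC) with the same factors over 72 h or more. Each of the 3 groups had 1 library, so no difference below has a replicate check, and no test with replicates compared the stages. The series presents its RNA as coming from exosomes, small vesicles that cells release. Its treatment text instead has cultures exposed to alendronate, a bisphosphonate drug, so that they shed apoptotic bodies, and the samples do not say which of these was sequenced.

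The tables listed 899 mature miRNAs. The pOC library held 5430426 assigned counts and the mOC library 7017707. At least 1 count was found for 803 miRNAs in pOC and for 840 in mOC, and 311 and 315 miRNAs had 50 or more. A count of 0 allowed up to 0.552 CPM (counts scaled to a library total of 1000000) in pOC and 0.427 CPM in mOC. The same 5 miRNAs led both libraries and took 39.2% of the counts in pOC and 36.6% in mOC. They were miR-146a-5p, miR-99a-5p, miR-21a-5p, let-7i-5p and miR-27b-3p. The first of these, a miRNA induced by inflammatory signalling, made up 10.1% of the pOC counts (95% exact binomial interval 10.04 to 10.09%) and 5.71% of the mOC counts (5.69 to 5.72%). miR-21a-5p, whose hairpin lies in an exon of Vmp1 (GRCm38, chromosome 11, 86584067 to 86584158), was the most abundant in mOC with 9.67% of the counts (9.64 to 9.69%), against 8.54% (8.52 to 8.57%) in pOC. BMM had no column under its own name. The tables set pOC and mOC against a library headed R, a letter that the labels do not spell out.

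The comparison of mOC with pOC addressed which miRNAs differ between the early and the late stage of osteoclast formation. Among the miRNAs higher in mOC was miR-142a-3p, a miRNA of blood cells. It had 1545 counts in pOC and 11961 in mOC, 5.99-fold more after scaling (95% interval 5.68 to 6.32). miR-223-3p, a myeloid miRNA, was 3.55-fold higher (3.18 to 3.98). On the lower side, miR-690 was 9.33-fold less abundant in mOC (7.28 to 12.1), with 520 counts in pOC and 72 in mOC, and miR-122-5p, the main miRNA of liver and a common one in serum, was 4.98-fold less abundant (4.78 to 5.19). At least 2-fold higher in mOC were 5 of 11 members of the let-7 family, while 13 of 18 miRNAs of the imprinted Dlk1-Dio3 region, 4 of 5 erythroid markers and 7 of 11 stromal markers were at least 2-fold lower.

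Of the 899 miRNAs, 49 were at least 2-fold higher in mOC and 69 at least 2-fold lower, with at least 10 counts over both libraries and a counting interval that excluded 1. Among the 337 miRNAs with 50 or more counts in a library, 40 were higher, 35 were lower and 77.7% lay within a 2-fold difference. The other large increases were seen for miR-455-3p (log2 ratio 2.23), miR-20a-3p (2.19), miR-331-3p (1.75), miR-28a-5p (1.73), miR-130b-5p (1.68) and miR-450a-5p (1.66). miR-455-3p, miR-20a-3p and miR-331-3p had only 10, 11 and 12 counts in pOC, and the interval of the first ran from 2.57-fold to 11.0-fold. Large decreases were also seen for miR-184-3p (-2.58), miR-412-5p (-2.56), miR-493-5p (-2.32), miR-379-5p (-2.20), miR-148a-3p (-2.13) and miR-143-3p (-2.10). In the GENCODE annotation of GRCm38, the hairpin of miR-142a-3p lies on chromosome 11 (87756864 to 87756927) in an intron of the long noncoding gene Mir142hg, that of miR-223-3p on chromosome X (96242817 to 96242926) in an exon of the antisense gene F630028O10Rik, that of miR-690 on chromosome 16 (28599935 to 28600043) in an intron of Fgf12, and that of miR-122-5p on chromosome 18 (65248861 to 65248926) in an exon of a long noncoding RNA.

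**Figure D1:**
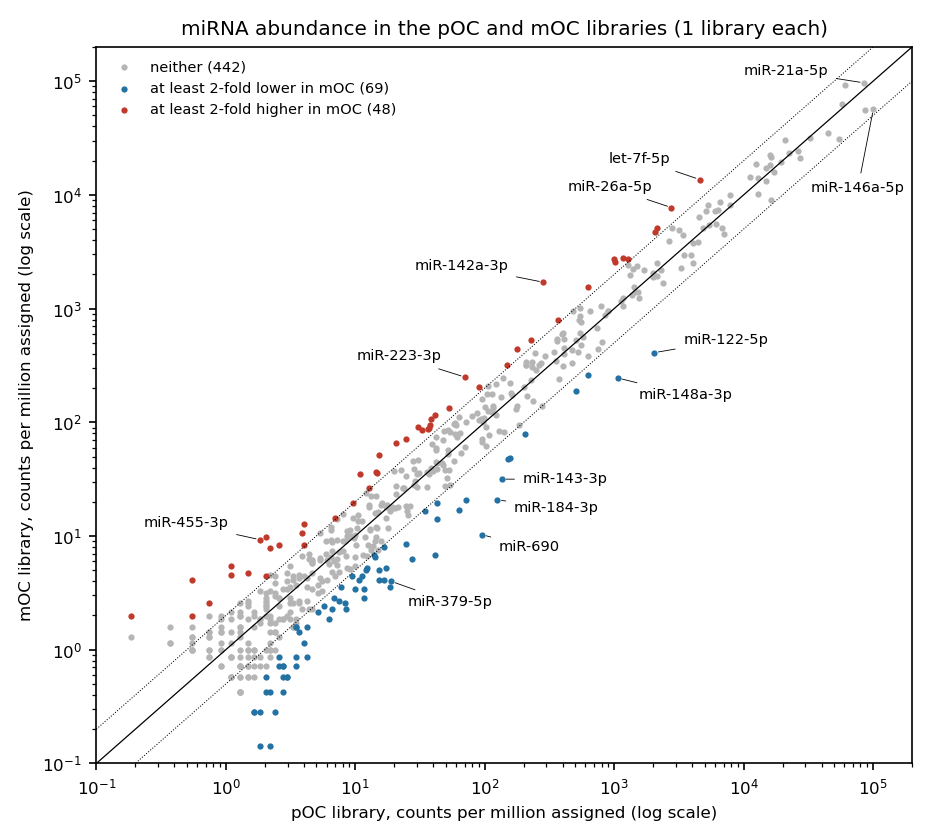
Abundance of each miRNA in the pOC library (x axis) and the mOC library (y axis), both in CPM on log scales, 1 point per miRNA for the 559 with a count in both libraries and at least 10 over both. The solid line marks equal abundance and the dotted lines a 2-fold difference. miR-142a-3p stands above the line at 5.99-fold, and miR-690 and miR-122-5p stand below it at 9.33-fold and 4.98-fold.

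Lists of related miRNAs, fixed before the data were examined, were compared by the median log2 ratio of their members. Of 26 lists, 3 had a median above and 3 a median below the central 95% of random lists of the same size and abundance. Chance alone would place 1.3 there if members varied independently. Neighbouring hairpins and near-identical sequences may move together, and chance would then place more lists outside. The let-7 family, whose members share a seed sequence and accumulate in differentiated cells, had a median of 0.61 (percentile 99.7). At least 2-fold higher were 5 of its 11 members, let-7f-5p (1.57), let-7d-5p (1.46), let-7e-5p (1.34), miR-98-5p (1.27) and let-7a-5p (1.09), and none was 2-fold lower. These near-identical sequences can share reads. The miR-30 family had a median of 0.75 (percentile 99.5) over 9 members, none of which differed 2-fold. The epithelial markers had a median of 0.99 (percentile 99.8), with 3 of 6 members higher, among them miR-200c-3p (1.37), and miR-141-3p lower (-1.21). These medians and the 3 that follow kept their sign under all 6 scalings tried.

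The Dlk1-Dio3 list had a median of -1.61, below every random list drawn, and 13 of its 18 measured members were at least 2-fold lower in mOC. miR-409-3p (-2.09), miR-381-3p (-1.89) and miR-369-3p (-1.27) were among them, the last with 3396 counts in pOC and 1818 in mOC. The hairpins of this list lie on chromosome 12 between 109590447 and 109743795. The erythroid markers had a median of -1.59 (percentile 0.180), with 4 of 5 lower, including miR-451a (2758 and 1321 counts, log2 ratio -1.43) and the paralogues miR-486a-5p (-1.66) and miR-486b-5p (-1.68), which cannot be counted apart with certainty. The stromal markers had a median of -1.32 (percentile 0.110), with 7 of 11 lower, miR-143-3p first. They did not all fall. The other 4 were within 2-fold: miR-199a-3p (0.09, from 4862 counts to 6687), miR-199a-5p (0.31), miR-152-3p (0.28) and miR-218-5p (-0.50). miR-127-3p belongs to both the Dlk1-Dio3 and the stromal list.

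miRNAs described as promoting osteoclast formation had a median of 0.20 (percentile 67.6; 0.06 to 0.47 over the 6 scalings). Of the 14 measured, miR-223-3p and miR-210-3p (1.34), a miRNA induced by low oxygen, were higher, and miR-148a-3p and miR-214-3p (-1.97, from 63 counts to 20) were lower. miRNAs described as restraining it had a median of -0.23 (percentile 3.24) and a mean of -0.04, and the median ran from -0.36 to 0.05 over the 6 scalings, so its sign depends on the scaling. Of these 16, miR-26a-5p (1.48) and the p53-induced miR-34a-5p (1.09) were higher, while miR-145a-5p (-1.32) and the epithelial marker miR-141-3p were lower. None of 14 miRNAs of inflammatory macrophages differed 2-fold, and their median was -0.01. The most displaced of them with at least 50 counts in a library were miR-146a-5p (-0.82), miR-9-5p (0.76), miR-222-3p (0.39) and miR-132-3p (-0.33). miR-155-5p stood at 0.04, miR-21a-5p at 0.18 and miR-23a-5p at -0.73. The myeloid list had a median of 0.51 (percentile 91.9), with miR-142a-3p and miR-223-3p higher and miR-322-5p at 0.79. The other arms of the same hairpins, miR-142a-5p (0.51) and miR-223-5p (0.49), were not 2-fold higher.

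The other lists stayed within the central 95%. The median was 0.21 for the miR-17~92 clusters, 0.27 for the miR-29 family, -0.10 for the miR-232724 clusters, 0.21 for the miR-181 family and 0.07 for the miR-183/miR-96/miR-182 cluster. It was 0.47 for the miR-99/let-7/miR-125 clusters, 0.20 for the miR-15/16 family, 0.15 for miR-221 and miR-222, -0.37 for the miR-34 family with other p53-induced miRNAs, and 0.22 for miRNAs often reported in vesicles. Among markers of other sources it was 0.07 for lymphoid cells, -0.26 for endothelium, 0.30 for platelets, -0.73 for liver and serum, -0.98 for muscle and 0.47 for neurons. The list of the Sfmbt2 cluster had 1 measured member, miR-466i-5p (-0.65), and no median. The hairpin matched to this member lies between genes on chromosome 13, outside Sfmbt2, so the value does not speak for the cluster.

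**Figure D2:**
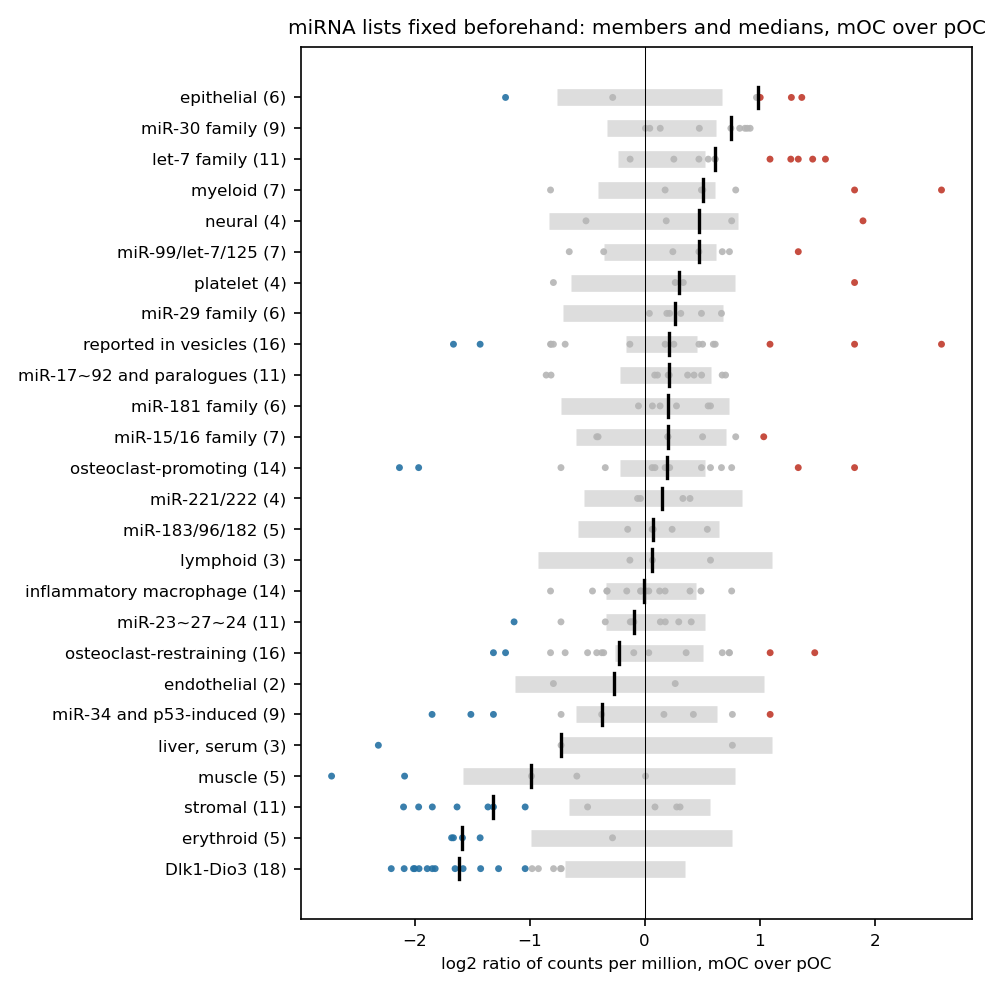
Log2 ratio of mOC over pOC for the members of 26 lists (1 point per miRNA, the number measured in brackets), with the list median as a black bar and the central 95% of the medians of random matched lists as a grey band. Members at least 2-fold higher are red and those at least 2-fold lower are blue. The Dlk1-Dio3, erythroid and stromal medians (-1.61, -1.59 and -1.32) lie left of their bands, and the let-7, miR-30 and epithelial medians (0.61, 0.75 and 0.99) lie right of theirs.

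The authors' deposited table of the same 2 libraries called 51 miRNAs higher and 71 lower in mOC, at an absolute log2 fold change of at least 1 and a p-value under 0.05. Its p-values rest on an assumed spread between libraries, since no replicate measured it. With the libraries scaled by the authors' own constants, 80 miRNAs were higher (62.0% of those called) and 49 lower, against 41.5% higher with the totals. In simulated pairs of these libraries without any difference, the rule called 8 miRNAs at a library-to-library coefficient of variation of 0.1 and 129.5 (median) at 0.4.

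The comparison of pOC with the library headed R was read from the authors' deposited table, because the counts of R are not used here. In the authors' deposited table miR-223-3p was 11.2-fold lower in pOC than in R, miR-342-3p 8.77-fold lower and miR-223-5p 6.81-fold lower. On the opposite side of the authors' deposited table stood miR-455-5p, 8.08-fold higher in pOC, miR-132-3p, which inflammatory signals induce, at 6.74-fold, and miR-99a-5p, already among the 5 most abundant, at 4.38-fold. The authors' deposited table called 59 miRNAs higher and 37 lower in pOC by the thresholds above. A 2-fold difference in the authors' deposited table, with no p-value, was seen for 174 higher and 164 lower. Among the 311 miRNAs with 50 or more counts in pOC, the authors' deposited table had 30 higher and 14 lower. That minimum, set on pOC alone, removes decreases more readily than increases, so these 2 numbers do not give the balance against R.

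Further large increases in pOC in the authors' deposited table were those of miR-1945 (5.36-fold), the p53-induced miR-34c-5p (4.56-fold), miR-2137 (4.03-fold), miR-493-5p (3.99-fold) and miR-92a-1-5p (3.65-fold). Lower in pOC in the authors' deposited table were also miR-210-3p (3.07-fold), miR-1839-3p (2.64-fold), miR-338-5p (2.30-fold), miR-3068-3p (2.24-fold) and miR-22-3p (2.21-fold). By list, the authors' deposited table put 4 of 26 medians above the central 95% of random lists and 0 below. Inflammatory macrophage miRNAs had a median of 0.69 in the authors' deposited table (percentile 99.9), with 5 of 14 at least 2-fold higher, including miR-212-3p (2.60-fold) and miR-155-5p (2.42-fold), and miR-9-5p at a log2 value of 0.91. Of these 5, 4 are arms of the neighbouring hairpins Mir132 and Mir212 on chromosome 11 (75173388 to 75173747), and the median of the other 10 members in the authors' deposited table was 0.15 (percentile 69.4), a calculation added after the values were seen. The miR-183/miR-96/miR-182 cluster, on chromosome 6, had a median of 1.15 in the authors' deposited table (percentile 99.6), with miR-183-5p 2.53-fold higher. For the stromal markers the median in the authors' deposited table was 0.70 (percentile 99.2), with miR-214-3p 2.44-fold higher, and for the miR-99/let-7/miR-125 clusters it was 0.49 (percentile 99.0), with miR-100-5p 2.85-fold higher.

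The remaining 22 medians for pOC from the authors' deposited table lay between -0.47 and 0.64, the highest that of the Dlk1-Dio3 list (percentile 96.75). They included, still from the authors' deposited table, the osteoclast-promoting list (-0.09; 3 higher and 3 lower of 14, miR-148a-3p 2.48-fold higher), the osteoclast-restraining list (0.28; 3 higher and 0 lower of 16, miR-34a-5p at -0.72) and the myeloid list (-0.45; 0 higher and 2 lower of 7). miR-21a-5p stood at -0.48 in the authors' deposited table, miR-142a-5p at -0.45 and miR-23a-5p at 0.86.

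The comparison of mOC with R, again from the authors' deposited table, was led by both arms of 1 hairpin, on chromosome 4 (63256851 to 63256932) in an intron of the collagen gene Col27a1. The authors' deposited table gave miR-455-3p as 27.8-fold higher in mOC, on 65 counts in mOC, and miR-455-5p as 17.7-fold higher, on 1430. miR-342-3p, from an intron of Evl on chromosome 12 (108658620 to 108658718), was 5.55-fold lower in the authors' deposited table, miR-223-5p was 4.97-fold lower and miR-223-3p 3.24-fold lower. Of all miRNAs, the authors' deposited table called 52 higher and 56 lower in mOC. A 2-fold difference in the authors' deposited table, with no p-value, was seen for 154 higher and 175 lower. Among the 315 miRNAs with 50 or more counts in mOC, the authors' deposited table had 38 higher and 19 lower. The minimum was again set without R and removes decreases more readily.

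Also higher in mOC in the authors' deposited table were miR-129-5p (9.61-fold), miR-132-3p (5.22-fold), miR-142a-3p (4.65-fold), miR-34b-5p (4.42-fold), miR-3473e (3.67-fold) and miR-34c-5p (3.42-fold). Also lower in the authors' deposited table were miR-690 (3.23-fold), the muscle miRNA miR-133a-3p (3.04-fold), miR-122-5p (2.89-fold), miR-143-3p (2.73-fold) and miR-381-3p (2.49-fold). By list, the authors' deposited table put 3 of 26 medians above the central 95% of random lists and 5 below. Above were, in the authors' deposited table, the miR-183/miR-96/miR-182 cluster (1.18, percentile 99.4, 4 of 5 members 2-fold higher), the miR-99/let-7/miR-125 clusters (0.96, percentile 99.9) and the let-7 family (0.87, percentile 99.9, 4 of 11). Below were, in the authors' deposited table, the muscle markers (-1.61, percentile 0.04), the erythroid markers (-1.21, percentile 0.210) and the Dlk1-Dio3 list (-1.10, 11 of 18 members 2-fold lower). The 5 muscle members had only 1 (miR-1a-3p) to 58 (miR-499-5p) counts in mOC. The stromal markers (-0.73, percentile 0.575) and the miRNAs reported in vesicles (-0.27, percentile 2.40) were below as well in the authors' deposited table.

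The remaining 18 medians for mOC from the authors' deposited table lay between -0.57 and 0.60. The inflammatory macrophage list was at 0.24 in the authors' deposited table (percentile 87.6), with 6 of 14 members higher, among them miR-9-5p (3.10-fold), miR-212-3p (2.77-fold) and miR-155-5p (2.41-fold). The same 4 arms were among the 6, and the other 10 members had a median of -0.16 in the authors' deposited table. The osteoclast-promoting list was at -0.23 in the authors' deposited table, with 2 higher and 1 lower of 14, miR-183-5p 2.57-fold higher and miR-148a-3p at -0.87. The osteoclast-restraining list was at 0.33 in the authors' deposited table, with 5 higher and 1 lower of 16, miR-7b-5p and miR-26a-5p each 2.26-fold higher. The myeloid list was at -0.34 in the authors' deposited table, with 1 higher and 2 lower of 7 and miR-322-5p at 0.52. miR-21a-5p stood at -0.34 in the authors' deposited table, miR-214-3p at -0.78 and miR-23a-5p at 0.08. Whether any of these differences from R was larger at 1 stage than at the other was not tested with replicates. That question comes down to mOC against pOC, given above with counting error or an assumed dispersion only. Both comparisons with R use the same library R, whose chance values they share.

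**Figure D3:**
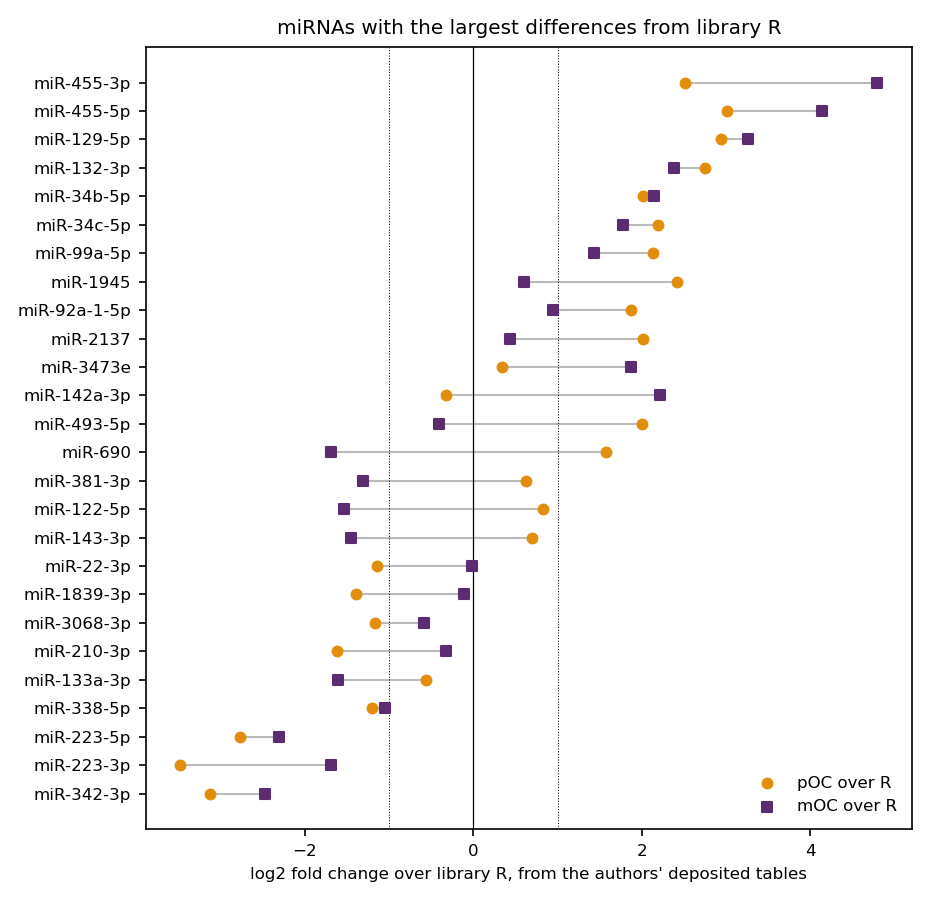
Log2 fold change over the library headed R for pOC (circles) and mOC (squares), as given in the authors' deposited table, for the 26 miRNAs with the largest differences by the rule fixed beforehand. All had at least 50 counts in pOC or mOC, so miRNAs abundant in R alone are absent. Dotted lines mark a 2-fold difference. miR-455-5p lies right of the lines at both stages (8.08-fold and 17.7-fold higher) and miR-223-3p left of them (11.2-fold and 3.24-fold lower), while miR-690 lies on opposite sides.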

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

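The tests on the first pattern below were all chosen after its values were seen, and so was the choice of the pattern. In the authors' deposited table, 35 miRNAs passed the thresholds against R at both stages, 33 in the same direction and 2 in opposite directions. Of the 33 in the authors' deposited table, 21 were higher and 12 lower. The shared library R alone can make calls agree, and the overlap it gives without any difference was not simulated because the counts of R are not used here. Of the 2 in opposite directions, miR-690 had a log2 fold change over R of 1.57 in pOC and -1.69 in mOC, and miR-412-5p had 1.17 in pOC and -1.45 in mOC. They stand out because the signs differ between the stages. Both were also among the largest decreases of mOC against pOC above, and no replicate measures that difference. The hairpin of miR-412-5p lies on chromosome 12 (109743289 to 109743368) in an exon of the long noncoding gene Mirg, inside the Dlk1-Dio3 region, and that of miR-690 in an intron of Fgf12.

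miR-412-5p belongs to a wider pattern, the lower Dlk1-Dio3, erythroid and stromal miRNAs in mOC. The tables argue against the choice among the 6 scalings tried as the cause, since none shifted the log2 ratios by more than 0.27. Under them the Dlk1-Dio3 median stayed at -1.34 or lower, the erythroid one at -1.32 or lower and the stromal one at -1.05 or lower. None of the 3 list medians was above percentile 0.18 of random lists of like abundance. The pattern was picked by those percentiles, so they are no separate test of low counts, which stay open. A larger share of RNA of the osteoclast lineage itself, which would lower all other cell types alike, stays open: the epithelial median was 0.99, but its members went both ways (miR-200c-3p 1.37, miR-141-3p -1.21). miR-141-3p had only 28 counts in pOC and 15 in mOC, and its hairpin lies in an intron of Gm15884, as does that of miR-200c-3p. A smaller share of RNA from 1 outside source, such as serum or cells carried over from marrow, may account for part of it and stays open: the log2 ratio of miR-451a exceeded that of miR-122-5p by 0.89, which 1 source allows only if the cells also make some of these miRNAs. A true difference between the stages stays open too, untested with 1 library each.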

How the results depend on the processing

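The settings with the authors' constants, larger dispersions, the authors' ratios unfiltered, a minimum of 10 counts against R and recentring, and a list without 2 hairpins, were chosen after the data were seen. The counts of mOC against pOC, 49 higher and 69 lower, stayed within 1.5 times under TMM factors, both median-ratio scalings, the top 5 miRNAs left out, pseudocounts of 0.5 and 5 and no count minimum (40 to 50 higher, 63 to 79 lower). The authors' constants shift all log2 ratios by 0.27 and turned the balance to 80 higher and 49 lower; median ratios over miRNAs with at least 100 counts shift them by -0.14. A threshold of 1.5-fold gave 95 higher; 4-fold gave 7 higher and 22 lower, by its construction. A minimum of 100 counts left 34 higher and 29 lower, as fewer miRNAs enter, so it turned the balance as well. The authors' log2 fold changes with no minimum and no interval gave 175 higher and 176 lower. Their calls, 51 and 71, became 8 higher and 22 lower at 4-fold and p under 0.01, and 9 higher and 22 lower with a dispersion of 0.16, where 0 of 899 adjusted p-values of the edgeR exact test were under 0.05 and 31 unadjusted ones were. At a dispersion of 0.04 they stayed at 46 higher and 61 lower, with 54 adjusted p-values under 0.05.

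Against R, 4-fold left 80 higher and 83 lower for pOC, and 81 higher and 73 lower for mOC, while 1.5-fold gave 239 higher for mOC. At least 10 counts in pOC left 66 higher and 25 lower, and at least 10 in mOC left 55 higher and 43 lower. Most 2-fold differences from R thus rested on under 10 counts in pOC or mOC. These minimums, set without R, remove decreases more readily than increases. At 4-fold and p under 0.01, the authors' calls fell to 14 higher and 6 lower for pOC and to 10 higher and 6 lower for mOC. Recentring kept all 4 counts within 1.5 times. The number of lists outside the central 95% (6, 4 and 8) was the same under the scalings, recentrings and pseudocount run on it. A shift of all miRNAs cannot alter it. Leaving out the arms of Mir132 and Mir212, for which it was not recounted, took the inflammatory macrophage list for pOC inside. The medians themselves moved by more than their counting spread in 13 of 26 lists of mOC against pOC under median ratios over miRNAs with at least 100 counts, and in 18 under the authors' constants. Over the 6 scalings 6 medians changed sign, among them that of the osteoclast-restraining list (-0.36 to 0.05), but none of those outside the central 95%. Recentring moved 4 medians for pOC and 8 for mOC against R. Without the arms of Mir132 and Mir212, the inflammatory macrophage median for pOC in the authors' deposited table moved from 0.69 to 0.15, inside the central 95%, and that for mOC from 0.24 to -0.16.

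Not run were scalings, pseudocounts, count minimums over both libraries and the top 5 left out for R, whose counts are not used here, predicted miRNAs left out, since none is listed, and leaving out a replicate. No paired analysis was possible because each group has 1 library. In simulated pairs with a coefficient of variation of 0.1, the rule called 42.5% of 2-fold changes, which lie at its threshold, 89.0% of 4-fold and 91.0% of 8-fold changes.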

Other observations

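The tests on the let-7 family were chosen after its values were seen, while the relations across hairpins were set down before their results.

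The higher let-7 family in mOC (median 0.61 for 11 members) is a pattern that technical causes could produce. Removing the linear trend of the log2 ratio on the GC content of the hairpin on the side of the arm (rho -0.11 across 330 miRNAs, which are not independent replicates) moved the median of the 9 members with a GC value from 1.09 to 1.05, above the upper limit of 0.59 for random lists treated the same way. Under 6 scalings the lowest median was 0.48, so scaling does not account for all of it. The GC test cannot settle that cause, because it used the GC content of part of the hairpin, not of the sequenced miRNA. It also left out let-7j and let-7k, which have no GC value, so its starting median of 1.09 is not the 0.61 of all 11 members. Reads shared between members stay open, because how such reads were counted is not given in the sources used here. The log2 ratios of let-7i-5p (0.614) and let-7j (0.612) were almost equal, as shared reads would make them. They may therefore not be separate measurements, while the ratios of all members span 1.70. Where the 3p arm of a let-7 hairpin was abundant too, it was not 2-fold higher. Its log2 ratio was 0.24 for let-7b, -0.08 for let-7d, -0.29 for let-7g, 0.19 for let-7i and 0.40 for miR-98. A difference between the stages stays open and untested.

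A first hypothesis was that hairpins within 10 kb on 1 strand, often made from a common transcript, move together. Over 44 neighbouring pairs outside the Dlk1-Dio3 region, the log2 ratios of mOC over pOC differed by a median of 0.45, against 0.69 for randomly paired hairpins (one-sided permutation test over 210 hairpins, p = 0.0169; adjusted p = 0.0338 over the 2 relations tested). Counting all 3 p-values computed, the adjusted p is 0.0507, so the result is borderline. Hairpins are not independent replicates.

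A second hypothesis was that both arms of a hairpin move together. Across 79 hairpins with both arms abundant, Spearman's rho was -0.02 (two-sided permutation p = 0.841, also after adjustment over the 2 relations; 95% bootstrap interval -0.25 to 0.20), and Pearson's r was 0.06 (permutation p = 0.610), or 0.04 without the 2 hairpins farthest from the median 5p value. This relation was therefore not found. In 52 hairpins with at least 100 counts of each arm in both libraries, a minimum chosen afterwards, rho was -0.07. The arms were over 1 log2 unit apart in 26 of the 79 hairpins. For the Mir142 hairpin the log2 ratio was 0.51 for miR-142a-5p and 2.58 for miR-142a-3p, and for the Mir331 hairpin -0.42 and 1.75. The Mir130b hairpin went the other way, with 1.68 for the 5p arm and -0.20 for the 3p arm.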
